A study of Bos taurus with 6 samples.

How the data were processed

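Transcript levels were measured on 6 two-colour oligonucleotide arrays, each carrying RNA of FGF8-treated and of control bovine granulosa cells in different dyes. Per the labels, RNA was isolated with a column kit made for very small samples, amplified in 2 rounds with T7 RNA polymerase, and coupled chemically to Cy3 or Cy5. The series design gives 3 biological replicates, and the titles give each replicate number once in each dye orientation, so the 2 arrays of a number were taken as a technical dye swap of 1 pair of RNA extracts. Nothing in the sources says whether the replicates came from separate animals or separate cultures, so the p-values of the gene tests measure the spread between these 3 samples. Per the labels, treated cells are those at 2 h and control cells those at 0 h, so the effect of FGF8 cannot be told apart from that of 2 h more in culture or of handling.

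Per the file headers, the scanner tables hold foreground and local background intensity per spot for the green Cy3 and the red Cy5 channel, not background-corrected. The scanner and image software are not given in the sources used here. The deposited values come as a column per array, and their scale, centring and direction were found by setting each column against that array's scanner values. The deposited values are log2 ratios of treated over control RNA on all 6 arrays: they correlated at 1.00 with the ratio of median foreground minus median background after loess, with slopes of 1.00. Their medians per array were 0.0025, 0.0030, 0.0018, -0.00085, 0.0063 and 0.0067. What else the authors did to make this table is not given in the sources used here.

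The median foreground intensity of each spot was used. A first fit on the mean foreground had been seen before this choice. The choice followed the deposited values, which the mean foreground treated in the same way matched at correlations of 0.689 to 0.842. Both statistics called 0 genes, with a smallest adjusted p per gene of 0.860 on the mean and 0.246 on the median.

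Background was corrected with limma's normexp method and an offset of 50, and each array was normalized by loess, with control spots at weight 0 and left out afterwards. The 143 probes marked as ignored on any array were left out. A probe was kept when it lay above the 95th percentile of the array's negative control spots in the treated RNA or in the control RNA on at least 4 of the 6 arrays, which left 27210 of 43794 probes. On the single arrays, 58.1 to 65.0% of probes were above background in the treated RNA and 59.7 to 65.4% in the control RNA. The number of arrays limits the precision.

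Gene names came from the platform annotation. It gives 1 symbol for 21790 probes, several for 0 and none for 22004, which are unnamed here. Of the named probes, 20025 carried a current symbol in the bovine RefSeq gene names, 1524 were updated through a synonym, and 241 matched neither and kept the name of the annotation. BHLHB2, an older name of BHLHE40, is among those left as they were, so BHLHE40 was not measured within its list. Each of the 11190 genes kept was represented by its brightest kept probe. Of 2585 genes with more than 1 kept probe, 1347 had probes of opposite sign.

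The sign of the arrays with control RNA in Cy5 was turned, the 2 arrays of each replicate were averaged, and the 3 resulting log2 ratios were tested against 0, two-sided, with lmFit and eBayes of limma, followed by Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. Averaging both orientations cancels a dye effect. Probe-specific dye effects were tested in the same way on the unturned means, in which the treatment cancels. Treated and control RNA of a number share an array, so the numbers pair them by design. In separate channels, the deviations of treated and control RNA from their group means correlated at 0.158, 0.364 and 0.341 within numbers and at -0.291 to 0.0728 across them. As the deposited array names were read, replicate 1 was on its own pair of slides and replicates 2 and 3 shared 1 slide; no label states the slide.

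Before the data were examined, 17 gene lists were fixed: FGF and ERK feedback, immediate early transcription factors, ovulatory cascade, steroidogenesis, cholesterol synthesis, granulosa cell markers, theca and stroma markers, endothelial markers, leukocyte and blood markers, cell cycle, apoptosis and GADD45, inflammatory and NF-kB targets, FGF ligands and receptors, TGF-beta and BMP targets, actin, SRF and YAP targets, stress and unfolded protein response, and ribosomal proteins. Each was tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 17 lists, and again with an estimated correlation and with fry. At the preset correlation, camera compares a list's genes with all other genes, so its p-values do not measure the spread between replicates. With an estimated correlation, it has no more than the 2 residual degrees of freedom that the replicates leave. List medians were set against 10000 random lists of the same size matched on intensity in 20 bins.

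The named genes were also fixed by rule. They are up to 12 called genes per direction with the largest change and the same sign on all 6 arrays, filled to 10 by the smallest unadjusted p where fewer were called. In each list up to 4 called members were added, or, where none was called, the 2 members with the smallest unadjusted p. SPRY2, SPRY4, DUSP6, ETV5, FOS, EGR1, NR4A1, CYP19A1, STAR and FSHR were named wherever measured. Names outside this rule are list members that passed after adjustment over their list, BHLHB2, which an alternative called, and genes chosen after their values were seen: ETV1, TNFAIP6, PTX3, PTGS2, AREG, ID1, ID2, the FGF8 transcript, TYROBP, LYZ and the members of the interferon and amino acid lists of the closing section.

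Other background corrections, normalizations, filters on dim probes, variance models, dye orientations, probe rules and thresholds, fits on all 6 arrays or on separate channels with and without a replicate block, the slide, the deposited values and the omission of each replicate were run as alternatives. The fit was tested on simulated data with the size of the real comparison (27210 probes, 11190 genes, 20 simulations). With 200 changed probes, it recovered 1.2% of those changed 1.5-fold, 42.9% at 2-fold, 91.3% at 3-fold and 96.1% at 4-fold. With 20 changed probes, it recovered 0% at 1.5-fold and at 2-fold, 32% at 3-fold and 61% at 4-fold. A list of 40 genes shifted by 0.2 on the log2 scale was called in 20 of 20 simulations, and 1 of 320 unshifted lists was called. The simulated genes varied independently, so these list counts do not cover real lists whose genes vary together. The estimated correlation was 0.158 for immediate early factors, 0.160 for ribosomal proteins and 0.634 for cholesterol synthesis. The versions were R 4.3.3, limma 3.58.1 and the data.table package, version 1.17.8.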

Results

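Granulosa cells, the somatic cells that line the follicle and make oestradiol, were taken from bovine follicles of 2 to 6 mm and kept for 5 days in serum-free medium with FSH and insulin, each at 10 ng/ml. The cells then received FGF8, a secreted growth factor that acts through FGF receptors and the ERK pathway, at 10 ng/ml for 2 h, and the series asks how this changed their transcripts relative to untreated cells. There were 3 biological replicates, each hybridised on 2 arrays with the dyes swapped. Median spot intensity was 110 to 163 in Cy5 and 108 to 192 in Cy3, against medians of 81 to 128 and 73 to 140 for the negative control spots. All ratios are log2 of FGF8-treated over control RNA, as mean ± SD over 3 replicates.

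Among the genes with the smallest p were early growth factor response genes. The 10 named here were chosen among genes higher in treated cells on all 6 arrays, which 392 of 11190 genes (3.50%) were. NR4A1, an orphan nuclear receptor made within minutes of stimulation, was 2.46-fold higher (1.30 ± 0.036, n = 3). SPRY2, an inhibitor of receptor tyrosine kinase signalling, was 2.93-fold higher (1.55 ± 0.25, n = 3), and EGR1, a zinc finger transcription factor, 2.78-fold (1.47 ± 0.29, n = 3). ADAMTS1, a protease of the follicle wall, was 2.49-fold higher (1.32 ± 0.25, n = 3), and HAS2, which makes hyaluronan, 2.34-fold (1.23 ± 0.21, n = 3). BAMBI, a decoy receptor for TGF-beta family ligands, was 2.74-fold higher (1.46 ± 0.37, n = 3). The protocadherin PCDH8 (1.19 ± 0.25), the kinase PLK2 (0.94 ± 0.11), the actin-binding protein XIRP1 (1.76 ± 0.64) and SPSB1 (0.82 ± 0.19) complete the first 10. None of them passed: limma called 0 genes and 0 probes over all probes tested, with adjusted p = 0.246 for NR4A1 and SPRY2 and 0.866 for SPSB1.

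On the side of lower values, AUP1, a protein of lipid droplets and the endoplasmic reticulum, was 2.23-fold lower (-1.15 ± 0.47, n = 3). ID3, a BMP-responsive inhibitor of transcription factors, stood at -0.69 ± 0.24, and CTSD, a lysosomal protease, at -0.84 ± 0.40. FANCL (-0.69 ± 0.26), OSBPL5 (-0.70 ± 0.27), SLC25A6 (-0.73 ± 0.34), B3GALT2 (-0.50 ± 0.052), RPL7A (-0.57 ± 0.20), SCO2 (-0.56 ± 0.20) and MYB (-0.64 ± 0.31) were also lower on all 6 arrays. That sign on all 6 arrays was a condition of the choice, which 278 genes (2.48%) met. Other probes of these genes were nearer to 0: among 5 probes of ID3 the value nearest to 0 was -0.19, and the second probes of B3GALT2 and SCO2 gave -0.23 and -0.066. All 10 had adjusted p = 0.866 in limma. At an unadjusted p under 0.05 there were 603 genes, 360 higher and 243 lower, where 559.5 are given by chance, and 87 of the 603 differed at least 1.5-fold (56 higher, 31 lower). This count of 87 became 267, 386 and 148 without replicates 1, 2 and 3, and lay between 9 with an intensity trend and 498 on the arrays with treated RNA in Cy5. A fit of all 6 arrays with the replicate number as a random block called 11 genes, ADAMTS1, AUP1, BAMBI, BHLHB2, EGR1, HAS2, NR4A1, PCDH8, PLK2, SPRY2 and XIRP1; a fit of the 6 arrays without the block called 15, the arrays with treated RNA in Cy5 alone called 7, and the fit without replicate 3 called 10. Both 6-array fits take their residual degrees of freedom from arrays, not from the 3 replicates. With the random block the standard error of SPRY2 was 0.161, against 0.136 in the original fit. Its unadjusted limma p still fell from 2.71e-05 to 5.55e-07. The arrays with treated RNA in Cy5 alone keep any dye effect in their ratios. The other alternatives called 0 genes at an adjusted p under 0.05. At an adjusted threshold of 0.10 there were also 0 named genes, while the unnamed probe EMBV3_13476 (2.77 ± 0.34, n = 3, chosen after its values were seen) had adjusted p = 0.0568 in limma.

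**Figure D1:**
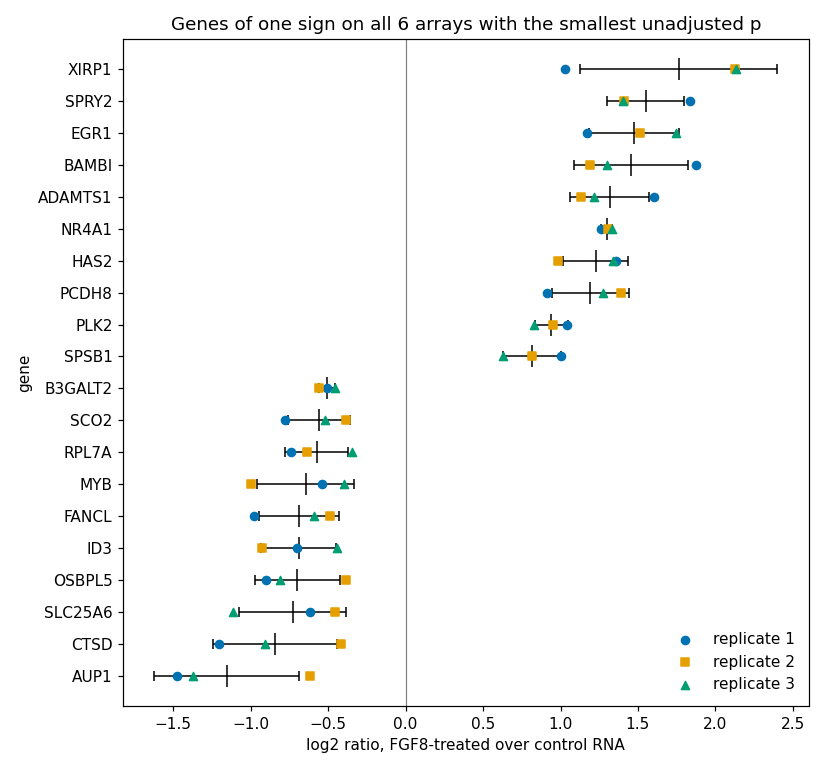
Log2 ratio of FGF8-treated over control RNA for the 10 higher and 10 lower genes with the smallest unadjusted p among genes of 1 sign on all 6 arrays, with points for the 3 replicates and bars for mean and SD. The means run from 1.76 for XIRP1 to -1.15 for AUP1, and none passed after adjustment over all probes.

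Genes of the FGF and ERK feedback list, which limit or mark ERK signalling, were higher as a group. Of 15 measured members, 5 rose when adjusted over the list alone (SPRY2, SPSB1, SPRY1 at 0.78, SPRED1 at 0.43 and FLRT2 at 0.41), 10 did not pass, and 0 passed over all genes. The Sprouty and Spred proteins restrain Ras and ERK, and FLRT2 is a membrane protein that interacts with FGF receptors. The members varied: DUSP6, an ERK phosphatase, had replicate values of -0.19, 0.17 and 2.00, ETV5, a transcription factor downstream of FGF, had -1.01, 0.35 and 0.86, and ETV1 averaged -0.54. SPRY4 had no kept probe. The list's median was 0.26 and its mean 0.31, with replicate medians of 0.0047, 0.29 and 0.48 (camera adjusted p = 0.000483). The call was lost, with adjusted p = 0.458 with an estimated correlation, 0.0532 after scale normalization, 0.0815 with an intensity trend and 0.0765 on the arrays with treated RNA in Cy5. That estimated correlation was -0.022, so members varying together do not account for the first of these losses.

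Immediate early transcription factors, which are induced without new protein synthesis, were higher as a group too. Of 25 measured members, 6 rose when adjusted over the list alone (NR4A1, EGR1, FOSL1 at 1.17, FOS at 1.04, KLF10 at 0.91 and BTG2 at 0.70), 19 did not pass, and 0 passed over all genes. FOS and FOSL1 are parts of the AP-1 transcription factor; FOS had replicate values of 1.62, 1.02 and 0.50, and its other probe gave 0.034. Values were higher on all 6 arrays for 9 members. Over its members the median was 0.38 and the mean 0.46, with replicate medians of 0.092, 0.37 and 0.61 (camera adjusted p = 1.55e-09). The call was lost with an estimated correlation only (adjusted p = 0.458 with an estimated correlation).

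The ovulatory cascade list holds genes that follicles switch on before ovulation. Of 20 measured members, 3 rose when adjusted over the list alone (ADAMTS1, HAS2 and PLAT, the tissue plasminogen activator, at 0.46), 17 did not pass, and 0 passed over all genes. TNFAIP6 and PTX3, which stabilise the hyaluronan matrix around the oocyte, had values of 0.87 and 0.72, while PTGS2, the inducible prostaglandin synthase, stood at 0.028 and the EGF-like ligand AREG at -0.18. Over the 20 genes the median was 0.10 and the mean 0.25, with replicate medians of 0.44, 0.037 and 0.14 (camera adjusted p = 0.00763). That median lay inside the central 95% of random lists matched on intensity (-0.094 to 0.11, percentile 97.0), as did those of replicates 2 and 3. The call was lost without replicate 1 (adjusted p = 0.0637), after scale normalization (0.113), with an intensity trend (0.241), on the arrays with treated RNA in Cy3 (0.0569), and with adjusted p = 0.458 with an estimated correlation. That correlation was -0.038, so members varying together do not account for the last of these losses.

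Ribosomal protein genes, which code for the structural proteins of the ribosome, were slightly lower as a group after loess, and higher than 0 with median centring of the arrays. Of 40 measured members, 0 passed when adjusted over the list alone and 0 over all genes, and 3 were lower on all 6 arrays. RPL7A stood at -0.57 and RPL8 at -0.54 ± 0.41 (n = 3). Their median was -0.11 and their mean -0.13, with replicate medians of 0.017, -0.12 and -0.34 (camera adjusted p = 0.000123, and adjusted p = 0.672 with an estimated correlation). With each array centred on its median in place of loess, the list's median turned to 0.051 (adjusted p = 0.506), where the median of all genes was 0.046. The call was also lost without replicate 3 (0.0635) and on the arrays with treated RNA in Cy5 (0.457).

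Targets of TGF-beta and BMP signalling went both ways. Of 11 measured members, 3 passed when adjusted over the list alone and 0 over all genes: BAMBI and SKIL, a repressor of SMAD proteins at 0.53, rose, and ID3 fell, at -0.69 on its brightest probe and -0.36 as the mean of its 5 probes. The other 8 did not pass, among them ID2 at 0.52 and ID1 at -0.052. The list's median was 0.11 and its mean 0.20 (camera adjusted p = 0.0924).

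No gene of steroid synthesis or granulosa identity passed the test. CYP19A1, the aromatase that makes oestradiol, had replicate values of 0.33, -0.89 and -0.12, and its other probe averaged 0.033. STAR, which moves cholesterol into mitochondria, averaged 0.29 ± 0.49 and FSHR, the FSH receptor, 0.28 ± 0.25 (n = 3 each; FSHR -0.013 with treated RNA in Cy3). In steroidogenesis, TSPO (-0.43) and the nuclear receptor NR5A2 (-0.45, with 0.055 at the other end of its 3 probes) had the smallest p, and 0 of 12 members passed when adjusted over the list alone or over all genes. Its median was 0.016, its mean -0.030 and its test pointed down (camera adjusted p = 0.736). Among granulosa cell markers, FST, which binds activin, stood at 0.48 ± 0.32. IHH averaged -0.32 ± 0.15 (n = 3) but was higher on 3 of 6 arrays and turned with the dyes, at -1.03 with treated RNA in Cy5 and 0.39 with treated RNA in Cy3. Of these markers 0 of 17 passed when adjusted over the list alone or over all genes (median 0.034, mean 0.021, camera adjusted p = 0.978). Replicate medians of the granulosa markers were 0.33, -0.18 and -0.12, and without replicate 1 the list's median turned to -0.16 (camera adjusted p = 0.0373). That call used the preset correlation of 0.01, where the estimated one was 0.351.

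Markers of other cell types that a granulosa preparation could hold showed no shift past the threshold. Theca and stroma markers had a median of -0.024 and a mean of -0.041 over 14 genes (camera adjusted p = 0.445), with MYH11, a smooth muscle myosin, at -0.23 and PDGFRB at -0.18. Endothelial markers had a median of 0.058 and a mean of 0.074 over 9 genes (camera adjusted p = 0.357), with ENG and CLDN5 both at 0.14 (ENG -0.15 with treated RNA in Cy3, CLDN5 -0.086 with treated RNA in Cy5). Leukocyte and blood markers had a median of -0.032 and a mean of -0.061 over 12 genes (camera adjusted p = 0.359), with CD68 at -0.37 and PTPRC at -0.23 (0.015 with treated RNA in Cy5). In each of these lists 0 members passed when adjusted over the list alone and 0 over all genes.

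Cholesterol synthesis genes differed in sign between replicates, with medians of 0.28, -0.31 and 0.27 over 19 genes. INSIG1, a sterol sensor, had replicate values of 0.28, 0.0098 and 1.76, while its 3 probes ranged from -0.17 to 0.68, and SC5D averaged 0.29. The list's median was 0.058 and its mean 0.11 (camera adjusted p = 0.357), and 0 members passed when adjusted over the list alone or over all genes. Without replicate 2 the list was called higher by camera at the preset correlation of 0.01 (median 0.19, adjusted p = 0.000432). The estimated correlation was 0.634, and with it the fit of all replicates gave camera adjusted p = 0.944.

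In the apoptosis and GADD45 list, MCL1, which protects from cell death, stood at 0.72 ± 0.34, with 0.32 as the lowest of 3 probes, and GADD45A, a stress-induced growth arrest gene, at 0.76 ± 0.55 (n = 3 each). The list's median was 0.12 and its mean 0.14 over 19 genes (camera adjusted p = 0.0684), and without replicate 1 it was called higher (adjusted p = 0.0198). Among actin, SRF and YAP targets, CCN2, a matricellular protein, had replicate values of 0.43, 1.38 and 1.85, and ANKRD1 stood at 0.47 ± 0.13. The median of this list was 0.087 and its mean 0.18 over 17 genes (camera adjusted p = 0.122), and without replicate 1 it was called higher (adjusted p = 0.000159). In both lists 0 members passed when adjusted over the list alone and 0 over all genes.

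The inflammatory and NF-kB list held lower values for the chemokine CXCL2 (-0.55 ± 0.22, with -0.13 nearest to 0 among 4 probes) and the cytokine IL1A (-0.59 ± 0.47), with a median of -0.018 and a mean of -0.051 over 11 genes (camera adjusted p = 0.357). Without replicate 3 it was called lower at the preset correlation of 0.01 (camera adjusted p = 0.0462), where the estimated one was 0.070. Among FGF ligands and receptors, the heparan sulphate proteoglycans SDC4 and GPC1 stood at 0.73 ± 0.44 and -0.83 ± 0.71, and the FGF8 transcript itself at -0.18. The median of these 10 genes was 0.029 and their mean 0.0084, while the test pointed down (camera adjusted p = 0.978). Cell cycle genes had a median of 0.051 and a mean of 0.034 over 29 genes (camera adjusted p = 0.822), with the inhibitor CDKN1A at 0.43 and the checkpoint kinase BUB1 at -0.25. Stress and unfolded protein response genes had a median of 0.0092, a mean of -0.056 and a test that pointed down over 19 genes (camera adjusted p = 0.761), with the chaperones HSPA8 at 0.24 and HSPB1 at 0.22 (-0.41 with treated RNA in Cy5). In these 4 lists 0 members passed when adjusted over the list alone and 0 over all genes. Against random lists matched on intensity, the medians of FGF and ERK feedback (percentile 99.99), immediate early transcription factors (100) and apoptosis and GADD45 (98.7) lay above the central 95%, that of ribosomal proteins (0.79) lay below it, and those of the other lists lay inside. Over the 17 lists, fry, which asks whether genes move 1 way without reference to other genes, gave an adjusted p no smaller than 0.267; its test for change in either direction passed for FGF and ERK feedback (adjusted p = 0.00493) and immediate early transcription factors (adjusted p = 0.0249).

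**Figure D2:**
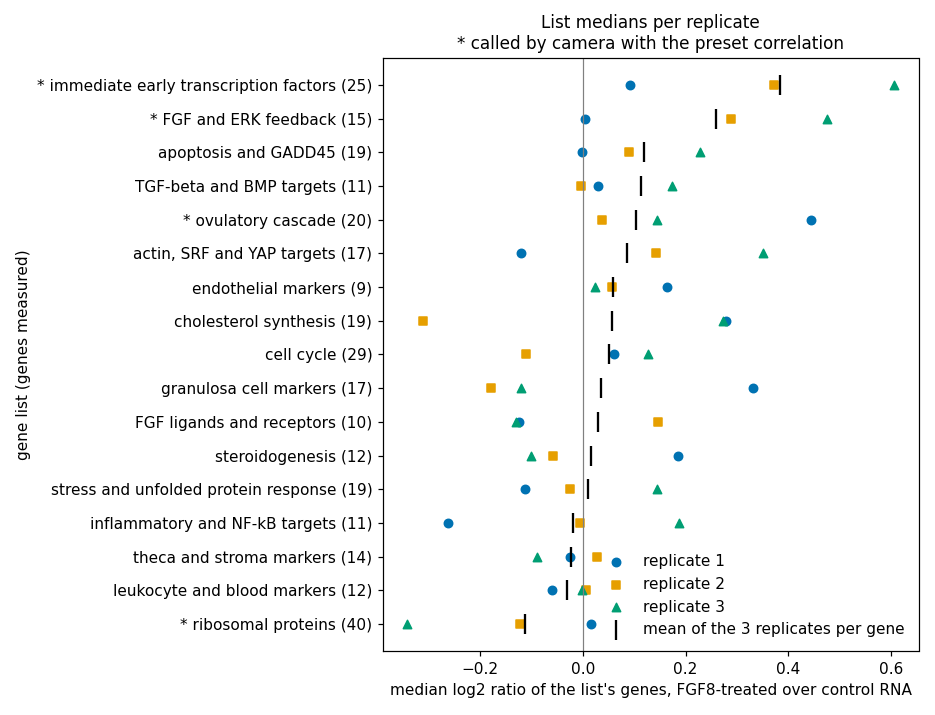
Median log2 ratio of FGF8-treated over control RNA for each of the 17 gene lists, with points for the 3 replicates and the median of the mean ratios marked. The 3 replicate medians are 0.092, 0.37 and 0.61 for immediate early transcription factors and 0.28, -0.31 and 0.27 for cholesterol synthesis.

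Across all probes the replicates had little in common. Between replicates, Pearson's r of the ratios was 0.0030, -0.00042 and 0.109 and Spearman's rho -0.034, 0.045 and 0.099; these are across probes, which are not independent replicates. Between the 2 dye-swapped arrays of a replicate, r was 0.540 in replicate 1, -0.109 in replicate 2 and 0.484 in replicate 3. The SD of the gene ratios was 0.350, 0.227 and 0.461 in the 3 replicates. A dye effect was called by limma for 2036 of 27210 probes (7.48%), with 1103 brighter in Cy5 and 933 in Cy3. The median absolute dye effect was 0.11 on the log2 scale, as was the median absolute ratio of treated over control RNA.

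**Figure D3:**
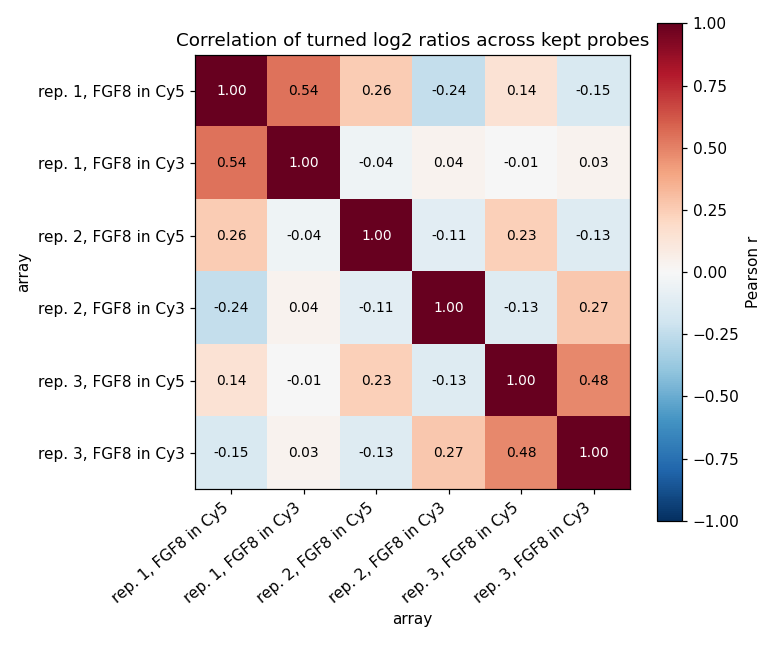
Pearson correlation across probes of the log2 ratios, turned to treated over control, for each pair of the 6 arrays. The dye-swapped pairs of replicates 1, 2 and 3 stand at 0.540, -0.109 and 0.484, and arrays of different replicates at 0.033 to 0.273 in the same orientation and -0.240 to -0.0060 in the opposite one.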

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

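The test of whether the dyes of replicate 2 were recorded the wrong way round was chosen after its correlation had been seen; the other tests here were written before their results.

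A difference between the dye orientations was found for 2036 probes, whose Cy5 over Cy3 ratio departed from 0 whichever RNA carried which dye. With the sign of 1 replicate turned the highest count was 0, so 1 of the 4 sign sets, the real one, gave as many; 4 sets are too few for a share under 0.05. The swap removes this effect from the mean of both orientations, not from single arrays.

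A signal outside the main measurement came from the positive control spots named E1A, whose lowest median Cy5 intensity over the arrays was 9509.5, against 81 to 128 for the negative control spots. Over the 320 E1A spots, raw log2 ratios of the treated over the control channel were -0.12, 0.19 and -0.044 with treated RNA in Cy5 and -0.70, -0.58 and -0.42 with treated RNA in Cy3.

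The arrays of replicate 2 correlated at -0.109, where those of replicates 1 and 3 correlated at 0.540 and 0.484. Dyes recorded the wrong way round on 1 array would also turn the early response genes, yet across 40 feedback and immediate early genes the 2 arrays correlated at 0.565, and 30 had the same sign on both, which argues against that explanation. Probe-specific dye bias on top of a small difference between the RNAs may account for it: with each probe's dye effect from replicates 1 and 3 subtracted, the correlation rose to 0.0712. The same step, with the dye effect taken from the other replicates each time, moved replicate 1 from 0.540 to 0.380 and replicate 3 from 0.484 to 0.579. What gave replicate 2 the smallest spread of ratios (SD 0.227) stays open; its feedback and immediate early medians, 0.29 and 0.37, lay above those of replicate 1 (0.0047 and 0.092) and below those of replicate 3 (0.48 and 0.61).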

How the results depend on the processing

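The alternative with the mean foreground was chosen after seeing the data. The estimated inter-gene correlation was planned beside the preset one, and was counted among the alternatives only after seeing the data. Except where the construction is named, the cause was not tested.

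The count of called genes was 0, and rose to 11 with all 6 arrays and the replicate number as a random replicate block, to 15 with no replicate block, which counts dye-swapped arrays as independent, to 7 on the arrays with treated RNA in Cy5, and to 87 at an unadjusted p under 0.05 with 1.5-fold. Both 6-array fits take their residual degrees of freedom from arrays, not from replicates. Without each replicate in turn the count of called genes ran from 0 to 10. The paired fit on separate channels, with a fixed replicate block, called 0 genes and 6 lists. Its probe ratios and probe tests equal those of the original fit, so the 0 genes followed from the construction. The gene values were not all the same, with 604 genes at an unadjusted limma p under 0.05 against 603 in the original fit. Lists in the 6-array, separate-channel and slide fits were tested with cameraPR on the genes' t-statistics in place of camera. Their list counts therefore also reflect a change of test. The count of shifted lists was 4, and became 7 in both 6-array fits and in separate channels with no replicate block, 2 after scale normalization, with an intensity trend and on the arrays with treated RNA in Cy5, and 0 with the estimated correlation. Adjusted p ran from 1.53e-08 to 0.458 over 22 alternatives for the feedback list (called in 18), from 1.06e-18 to 0.458 for immediate early factors (21), from 4.96e-06 to 0.458 for the ovulatory cascade (17) and from 2.01e-06 to 0.672 for ribosomal proteins (18).

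Apoptosis and GADD45 was called in 9 alternatives, TGF-beta and BMP targets in 7 and actin, SRF and YAP targets in 4. Calls by cameraPR are among these, and all were made at the preset correlation. In separate channels with a fixed replicate block the medians of the apoptosis and TGF-beta lists were those of the original fit. There cameraPR called both, at adjusted p = 0.0388 for apoptosis and 0.0130 for TGF-beta. The count of dye-affected probes was 2036, and became 476 with an intensity trend, 8340 on the mean foreground, 504 with an offset of 10 and 0 after scale normalization, and ran from 839 to 2395 without each replicate. The mean correlation between replicates, 0.0373, moved by less than its SD of 0.0624 in all alternatives run for it.

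Of 51 named genes, 42 kept their sign in all alternatives, and 18 of 1071 values were of the other sign. Many of these values could not turn. Genes named for having the same sign on every array keep it when a replicate or a dye orientation is left out. An intensity trend, Aquantile and the fits on all arrays or on separate channels leave the log2 ratio of each probe unchanged by construction. The counts therefore measure stability only for the remaining values. ETV5 was -0.00041 in the deposited values, -0.023 on the mean foreground, -0.011 without background correction, -0.11 on arrays with treated RNA in Cy5, -0.61 after scale normalization and -0.20 with the slide as a separate mean. With treated RNA in Cy5, CLDN5 was -0.086, HSPB1 -0.41 and PTPRC 0.015. With treated RNA in Cy3, ENG was -0.15, FSHR -0.013 and IHH 0.39, and IHH was 0.026 after scale normalization. Without each replicate, CLDN5 ran from -0.0041 to 0.26, CYP19A1 from -0.51 to 0.10, DUSP6 from -0.011 to 1.09 and ETV5 from -0.33 to 0.61.

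The direction of the test turned 29 times, in lists of which none was called in the original fit; list medians follow. FGF ligands and receptors had 0.029 with an intensity trend and in separate channels with a fixed replicate block, 0.039 without a filter, 0.10 with treated RNA in Cy3, 0.022 after scale normalization, and -0.051 to 0.037 without each replicate. Granulosa cell markers had 0.034 after Aquantile, with the mean of a gene's probes and in separate channels with and without the block, 0.0032 on the mean foreground, -0.11 with treated RNA in Cy3, and -0.16 to 0.18 without each replicate. The steroidogenesis list had 0.066 on the mean foreground, 0.056 with treated RNA in Cy3, -0.020 with the slide as a separate mean, and -0.074 to 0.071 without each replicate. Stress and unfolded protein response had 0.023 with the mean of a gene's probes, 0.083 with median centring, 0.0039 with treated RNA in Cy3, 0.061 after scale normalization, and -0.069 to 0.091 without each replicate. Cell cycle had 0.059 with treated RNA in Cy5 and -0.0041 to 0.13 without each replicate, endothelial markers 0.040 with median centring, cholesterol synthesis -0.0078 to 0.19 and inflammatory and NF-kB targets -0.098 to 0.092 without each replicate.

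About 58.1 to 65.4% of probes lay above background per array and RNA, and the probes left out as dim entered the fit without a filter on dim probes, which called 0 genes and 6 lists.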

Other observations

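The interferon and amino acid lists below, and the tests of a response to FGF8 in the same direction in all cultures and of a ribosomal shift in 1 replicate alone, were chosen after the values had been seen; the remaining tests were written before their results.

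Interferon-stimulated genes, which cells switch on against viruses, had opposite ratios in different replicates. Of 36 measured genes, 34 were lower in treated cells in replicate 1 and 34 higher in replicate 3, 32 of them both, with list medians of -0.71 and 1.04; in replicate 2 the median was -0.032 and 20 were lower. GBP5, an interferon-induced GTPase, had -3.66, -0.25 and 2.80 in replicates 1, 2 and 3, the chemokine CXCL10 -2.76, -1.26 and 2.25, and IFI27 -2.53, 0.13 and 2.13. In the mean of the replicates the list's median was -0.042. Of these genes 1, IRF1, stands in a list fixed beforehand.

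Genes of amino acid synthesis and of the ATF4 response to amino acid shortage were lower in treated cells of replicate 1, with 23 of 27 below 0 and a median of -0.35, against medians of 0.017 in replicate 2 and 0.22 in replicate 3. In replicate 3, 20 were higher, 17 of them lower in replicate 1. In the mean of the replicates the median was -0.11, at percentile 0.10 of random lists matched on intensity. The list was assembled after these ratios had been seen, so a percentile far from the middle was built in and is no test. The stress and unfolded protein response list, fixed beforehand and sharing some members, lay at percentile 49.4. PSAT1, an enzyme of serine synthesis, had -2.94, 0.011 and 0.56, and TRIB3, a target of ATF4, -2.39, 0.017 and 0.70. On the 2 arrays of replicate 1 the list's median was -0.88 and -0.10. Of these genes 6 stand in lists fixed beforehand. Cholesterol synthesis genes were lower in replicate 2 alone, where their median lay at percentile 0.00 of random lists matched on intensity, against 99.6 in replicate 1 and 99.1 in replicate 3. Random lists hold unrelated genes, while the estimated correlation of the cholesterol genes was 0.634. Their percentiles therefore overstate how unusual the medians are.

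For the interferon genes, an artifact of single hybridisations is argued against by the dye swaps: within replicates 1 and 3 both arrays had the same sign, and the smaller list median was at least 0.320 of the larger. Leukocytes in unequal share are argued against by their markers, with medians of -0.061 in replicate 1 and -0.0024 in replicate 3, both inside the central 95% of matched random lists and short of the interferon medians of -0.71 and 1.04. The 4 brightest went both ways: PTPRC and CD68 had -0.14 and -0.26 in replicate 1 and -0.66 and -0.84 in replicate 3, while TYROBP and LYZ had -0.35 and -0.049 in replicate 1 and 0.83 and 0.25 in replicate 3. A response to FGF8 in the same direction in all cultures would give like signs, and 32 of 36 genes were lower in replicate 1 and higher in replicate 3. The list was assembled after these opposite ratios had been seen, so this count restates the pattern and cannot decide. A response that differs between cultures stays open. A difference between treated and control cells of single replicates, such as an interferon response in some dishes, may account for the pattern; it was not tested.

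For the lower ribosomal protein genes, a bias with intensity was examined with random lists matched on intensity, among which the median lay at percentile 0.79. The central 95% of the random medians ran from -0.093 to 0.079, so other genes of like intensity were not lower as a group. With median centring in place of loess the ribosomal median lay at percentile 0.96, although the median itself was 0.051. In 2 replicates the median lay below the central 95% of matched random lists, replicate 2 at percentile 0.25 and replicate 3 at percentile 0.01. Random lists hold unrelated genes, while these genes vary together (estimated correlation 0.160). The percentiles therefore cannot decide whether the list departs from genes of like intensity, nor whether the shift is present in 1 replicate alone. The call rested on replicate 3: it was lost without it (camera adjusted p = 0.0635, over a range of 2.01e-06 to 0.672). Replicate medians lay below the median of all genes in 2 of 3, replicate 1 being at percentile 48.9. Whether FGF8 lowers these transcripts stays open.

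There are 4 sign sets: the real one and 3 with the sign of 1 replicate turned. The fit called 0 genes with the real signs and 0 at most with the others, and a count of 0 leaves nothing to compare. The real signs gave 4 shifted lists and the highest other set 6, and 2 of the 4 sets, the real one included, gave at least 4. For genes at an unadjusted p under 0.05 and 1.5-fold, the real count was 87 and the highest other 153, and 3 of the 4 sets, the real one included, gave at least 87. Both highest values came from turning replicate 1, which lay on other slides than replicates 2 and 3 as the deposited array names were read, with no label to state it; in replicates 2 and 3 alone, 267 genes passed those limits and 0 were called. A total of 4 sets is too few for a share under 0.05.

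The probe with the smallest p, EMBV3_13476, has no gene name here and was chosen after its values were seen. It was 6.82-fold higher in treated cells (2.77 ± 0.34, n = 3; replicates 2.39, 2.86 and 3.05), with adjusted p = 0.0568 in limma.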
